A study of Homo sapiens with 18 samples.

How the data were processed

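RNA was measured in 18 sequencing libraries of KBM7, a human chronic myelogenous leukaemia cell line, in 6 groups of 3: the solvent DMSO, the compounds dCeMM-1, dCeMM-2, dCeMM-3 and dCeMM-4 at 10 times their EC50, and THZ531 at 600 nM, all for 5 h. Libraries were made by poly-A enrichment with a total RNA kit, and a mix of synthetic ERCC and SIRV RNAs was added as spike-in. The labels state neither the amount of spike-in per cell or per amount of RNA nor whether the 3 libraries of a group came from separate cultures. A p-value here therefore measures the spread between these libraries only.

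The deposited values are raw read counts per gene, with no normalization, in 1 table per library. Each table also holds counts for 92 ERCC sequences and 7 SIRV genes, and 5 HTSeq summary counts of reads that were not assigned to a gene. The submitters' processing notes name Trimmomatic 0.32, STAR 2.5.2b, Picard and HTSeq 0.11.2 and the genome build GRCh38.p7, without roles or order. The strand setting and the use of molecular identifiers are not stated, so reads of genes that overlap on opposite strands cannot be told apart from the tables alone. Reads placed at several positions were left out of the gene counts, which affects gene families with near-identical copies such as histones, ribosomal proteins and mitochondrially encoded genes. Of 58051 gene identifiers, 57447 matched the GENCODE release 29 annotation, which gave symbols, gene types and positions, and 604 did not and carry their identifier only.

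Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr by group, which left 15055. Libraries were scaled by TMM on endogenous genes, and a quasi-likelihood model with robust estimation was fitted to all 18 libraries with 1 coefficient per group, which leaves 12 residual degrees of freedom and gave a common dispersion of 0.00439. There were 12 contrasts: each compound against DMSO, each dCeMM compound against THZ531, and dCeMM-2, dCeMM-3 and dCeMM-4 against each other at their matched multiple of EC50. THZ531 was given at a fixed concentration, so its dose is not matched to those of the others. Benjamini-Hochberg adjusted p-values (FDR) were taken over all 15055 genes within a contrast with a threshold of 0.05. TMM scaling holds the bulk of genes at a log2 fold change near 0, so its fold changes are relative to the other genes. The same model was also fitted with libraries scaled by their spike-in counts, and fold changes from it are named as such. Standard errors (SE) are those of the log2 fold change. Group levels are TMM-scaled CPM with SD over 3 libraries.

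Before the data were examined, 33 gene lists with 805 entries were fixed, which cover the reported targets of the compounds, RNA polymerase II transcription and RNA processing, DNA repair, stress responses, the cell cycle, housekeeping classes and markers of blood and tissue cell types. All 805 entries matched the annotation. Lists were tested with camera, a test of a list against the other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a contrast, and again with the correlation estimated from the data. The test fry and the alternatives of scaling, filtering, software and left-out libraries described in the closing section were run beside them. For each list the numbers of members past the threshold are given with adjustment over all genes tested and, where stated, adjusted over the list alone. A list's relative median is the median log2 fold change of its members minus that of all genes in the same fit.

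The rule for naming genes was also fixed before the data were examined. Against DMSO it takes the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold whose 3 treated libraries all lie on one side of the 3 DMSO libraries and whose mean is at least 5 CPM in the higher group. It adds up to 4 members with the lowest adjusted p of each list called by camera, and 12 genes in every comparison: CCNK, CDK12, CDK13, RBM39, DDB1, DCAF15, BRCA1, ATR, FANCD2, MYC, HEXIM1 and CDKN1A. Between compounds it takes the 5 largest rises and falls. Differences between compounds in the 12 genes carry 95% intervals from the SE and a t distribution with 12 degrees of freedom.

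Group values of a library, such as the spike-in share, were compared with DMSO by exact two-sided permutation tests, for which 3 libraries against 3 give a smallest possible p of 0.1. Gene length and structure were compared per library as the median log2 CPM change of genes spanning at least 100 kb minus that of genes spanning under 20 kb, and of single-exon minus multi-exon genes, over protein-coding genes. Change was taken from the mean of each gene over the 3 DMSO libraries, which centres those libraries on themselves. The permutation p of these medians is therefore not exact. Correlations of fold changes between compounds were set beside those of 100 simulated pairs of unchanged groups, since all compounds share the same 3 DMSO libraries. Gene counts per library ranged from 4598576 in DMSO replicate 3 to 17943571 in dCeMM-4 replicate 2, and spike-in counts from 7727 to 84595. Counting intervals given for single low counts are exact and cover counting error only.

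The fit was tested on simulated data drawn from the mean levels of DMSO, the estimated dispersions and the real library sizes, with 13913 genes tested. In that run it recovered 67.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, 2.79% of its calls were unchanged genes, and with no gene changed it made 0 calls among 13906. A list of 30 genes lowered 1.4-fold was found at a camera adjusted p of 1.27e-64 with 0 other lists called (13912 genes). Genes were drawn independently of each other, so this run does not test calls of lists whose members vary together. With every gene of 14008 lowered 3-fold, the median log2 fold change was -1.59 with spike-in scaling and -0.00 with TMM. Simulated spike-in counts followed library size with counting noise only, so the spread of real spike-in shares between libraries was not tested. The length measure returned -0.99 for a simulated 2-fold fall of long genes among 15055. No library was left out. Differential use of exons was not analysed here, since the tables hold 1 count per gene.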

Results

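The series measured polyadenylated RNA in KBM7 cells, a chronic myelogenous leukaemia line, after 5 h with DMSO, with 4 compounds coded dCeMM-1 to dCeMM-4 at 10 times EC50, or with THZ531 at 600 nM. Each of the 6 groups had 3 libraries. The title of the series names a search for small molecules that act as molecular glue degraders. Of these compounds, dCeMM-1 is known as a degrader of the splicing factor RBM39, and dCeMM-2, dCeMM-3 and dCeMM-4 as degraders of cyclin K (CCNK). THZ531 is known as a covalent inhibitor of CDK12 and CDK13, the kinases that cyclin K activates. The comparisons with DMSO ask what each compound did to the transcriptome, and those with THZ531 ask how far each dCeMM compound resembled kinase inhibition. Gene counts per library ranged from 4598576 to 17943571. DMSO replicate 3 was the shallowest, with 18325 genes detected against 22280 and 22971 in the other DMSO libraries. On the log2 CPM of all tested genes, the leading principal component held 61.8% of the variance and the next 20.5%.

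Spike-in RNA took a larger share of the libraries after 3 of the treatments. It made up 0.179% ± 0.0200 of gene and spike-in counts in DMSO, 0.512% ± 0.0784 with dCeMM-2, 0.542% ± 0.0699 with dCeMM-3 and 0.531% ± 0.0992 with THZ531 (SD, n = 3 each). Every library of these 3 groups lay above every DMSO library (exact permutation p = 0.1 each, the smallest possible). The share was 2.86, 3.02 and 2.96 times that of DMSO. With dCeMM-4 it was 0.234% ± 0.0497, 1.31 times that of DMSO (exact p = 0.2), and with dCeMM-1 0.176% ± 0.0193 (exact p = 1). ERCC sequences alone gave ratios of 2.93, 3.08, 2.99, 1.34 and 0.988 for dCeMM-2, dCeMM-3, THZ531, dCeMM-4 and dCeMM-1, and SIRV genes alone 2.80, 2.98, 2.93, 1.28 and 0.982. When libraries were scaled by spike-in counts, the median log2 fold change of all genes moved by -1.77 with dCeMM-2, -1.81 with dCeMM-3, -1.84 with THZ531, -0.56 with dCeMM-4 and 0.07 with dCeMM-1. The direction of many genes therefore depends on the scale, and fold changes are given relative to the other genes (TMM) unless the spike-in scale is named. The labels do not say whether the spike-in was added per cell or per amount of RNA.

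**Figure D1:**
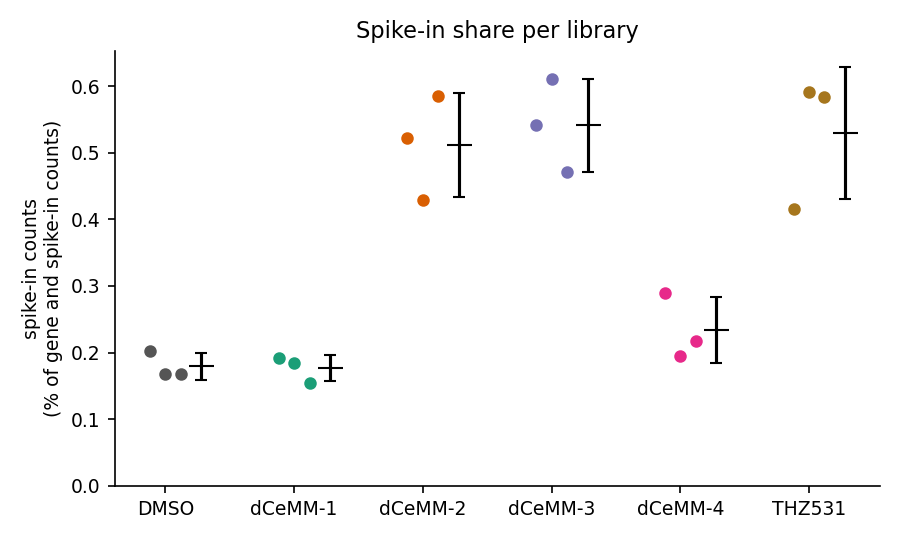
Spike-in counts as a percent of gene and spike-in counts (vertical axis) in each library (points) by group, with the mean and SD of 3 libraries as black bars. The libraries of dCeMM-2, dCeMM-3 and THZ531 average 0.512%, 0.542% and 0.531% against 0.179% in DMSO.

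Mitochondrially encoded transcripts took 5.14% ± 0.662 of gene counts in DMSO, 12.9% ± 2.25 with dCeMM-3 and 9.75% ± 2.70 with THZ531 (SD, n = 3, exact permutation p = 0.1 for both). They took 7.03% ± 2.01 with dCeMM-2 (exact p = 0.2), 6.13% with dCeMM-4 (exact p = 0.4) and 5.26% ± 0.482 with dCeMM-1 (exact p = 0.9). The 10 most abundant genes of a library held 5.50% ± 0.345 of gene counts in DMSO and 12.6% ± 1.63 with dCeMM-3.

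With dCeMM-1, the largest rise was that of CYP1B1, a cytochrome P450 of steroid and xenobiotic metabolism on chromosome 2 (38066973 to 38109902, minus strand, GRCh38), by 3.59 on the log2 scale (SE 0.11, adjusted p = 1.99e-24), from 6.38 ± 1.45 to 79.6 ± 3.04 CPM (SD, n = 3). TIPARP, an ADP-ribosyltransferase, rose by 1.43 (SE 0.10). SESN3 and ARRDC3, both known as FOXO target genes, each rose by 1.49 (SE 0.12 and 0.14). RSRP1 rose by 1.56, ZBED8 by 1.75 and LPAR6 by 1.42. The falls were led by the immediate early transcription factors EGR1, which fell by 3.05 (SE 0.11, adjusted p = 2.15e-22), and FOS, which fell by 2.85 (SE 0.15). RBM14, a paraspeckle protein gene whose annotation overlaps the readthrough gene RBM14-RBM4, fell by 1.82. BMX, DDN, FOSB and P2RY14, which lies opposite MED12L, were lower at -1.54, -1.54, -1.42 and -1.86. RBM39 mRNA, encoding the splicing factor that dCeMM-1 is known to degrade, rose by 0.84 (SE 0.07, adjusted p = 1.81e-11), from 314 ± 4.69 to 561 ± 12.7 CPM. The ligase receptor DCAF15 had a log2 fold change of 0.05 (SE 0.09, adjusted p = 0.722).

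Of 22 measured MYC target genes, mostly ribosome biogenesis factors, 19 fell and 0 rose with dCeMM-1 (21 fell when adjusted over the list alone), with a relative median of -0.60 and a camera adjusted p of 4.38e-17 (3.51e-05 with an estimated correlation). With spike-in scaling 7 of the 22 were called lower. NOLC1, NOP56, MYBBP1A and DKC1 were at -0.88, -0.86, -0.85 and -0.81 (SE 0.06, 0.06, 0.07 and 0.06), and MYC itself fell by 0.45 (SE 0.06, adjusted p = 1.93e-07). Of 17 heat shock genes, 14 fell and 0 rose, with FKBP4 at -0.72 and HSPA8 at -0.45 (camera adjusted p = 5.92e-09, adjusted p = 0.0762 with an estimated correlation). Smaller downward calls covered the unfolded protein response (7 of 20 fell and 1 rose, XBP1 at -0.68, camera adjusted p = 0.00513, adjusted p = 0.195 with an estimated correlation) and cholesterol genes (7 of 22 fell and 2 rose, camera adjusted p = 0.0134, adjusted p = 0.0762 with an estimated correlation). They also covered NF-kB targets (9 of 16 fell and 1 rose, NFKBIE at -0.90, camera adjusted p = 0.0409, adjusted p = 0.197 with an estimated correlation) and ATF4 targets (9 of 20 fell and 2 rose, STC2 at -0.62, camera adjusted p = 0.0419, adjusted p = 0.204 with an estimated correlation). Spike-in scaling called 1 heat shock gene, 1 unfolded protein response gene, 0 cholesterol genes, 1 NF-kB target and 0 ATF4 targets lower. The call of the ATF4 list was lost without DMSO replicate 1, DMSO replicate 2 or dCeMM-1 replicate 3 (camera adjusted p = 0.0507, 0.0602 and 0.0874). That of the NF-kB list was lost without DMSO replicate 2 or dCeMM-1 replicate 1 (camera adjusted p = 0.0666 and 0.0506). Among 33 SR and hnRNP splicing factors 9 rose and 6 fell (camera adjusted p = 0.473). In all, 4711 of 15055 genes passed the threshold, 2482 higher and 2229 lower, of which 409 changed at least 2-fold. Which direction holds more genes depends on the scale: DESeq2 size factors inside edgeR gave 2158 higher and 2535 lower, and DESeq2 1847 and 2393. With spike-in scaling 628 passed, 426 higher and 202 lower, and 0 calls changed direction.

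THZ531 raised the CDK inhibitor CDKN1A, a p53 target on chromosome 6 (36676460 to 36687339, plus strand), by 4.71 on the log2 scale (SE 0.08, adjusted p = 1.05e-34), from 19.4 ± 0.919 to 504 ± 19.6 CPM (SD, n = 3). Its rise on the spike-in scale was 2.86. The immediate early genes IER3 and ARC rose by 6.25 (SE 0.40) and 6.07 (SE 0.17), RASD1 by 5.96, IER5L by 4.45, C11orf96 by 4.04, and the TNF receptor family genes EDA2R and TNFRSF10D by 4.30 and 4.23. Without DMSO replicate 2 the rises of IER3 and EDA2R were 7.43 and 4.94, and without DMSO replicate 1 that of EDA2R was 3.65. The largest falls were those of ZNF786 (-5.27, SE 0.26), ZNF57 (-5.25), EFNA4 (-5.01), PPP1R10 (-4.79), PARS2 (-4.59), ZNF583 (-4.58) and USP2 (-4.56), all below 1 CPM after treatment. GTF2E1, a subunit of the general transcription factor TFIIE, was at -4.53 (SE 0.13). ZNF57 was at -6.05 without THZ531 replicate 1. CDK12 and CDK13, the known targets of THZ531, fell in mRNA by 1.38 and 0.81 (SE 0.07 each), and MYC fell by 1.51 (SE 0.06). Among DNA repair genes BRCA1 (chromosome 17, 43044295 to 43170245, minus strand) fell by 1.48 (SE 0.11) and ATR by 1.58 (SE 0.09), whereas FANCD2 rose by 0.68 (SE 0.13) relative to the other genes and was at -1.15 on the spike-in scale.

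Of 26 p53 target genes 15 rose and 4 fell with THZ531, with PMAIP1, TNFRSF10B and ZMAT3 higher by 2.63, 1.88 and 1.59 (camera adjusted p = 0.0098, adjusted p = 0.238 with an estimated correlation), and on the spike-in scale only 2 of the 26 were higher and 19 lower. Mitotic genes fell in 26 of 30 cases and rose in 1 (relative median -1.10, camera adjusted p = 1.06e-05, adjusted p = 0.231 with an estimated correlation), among them TTK at -3.03, AURKA at -2.47 and CCNB1 at -2.39. Of 30 genes of homologous recombination and the DNA damage response 22 fell and 4 rose (camera adjusted p = 0.0034, adjusted p = 0.279 with an estimated correlation), including PALB2 at -3.06 and TOPBP1 at -2.25. Of 26 elongation kinases and regulators 21 fell and 2 rose (camera adjusted p = 0.00799, adjusted p = 0.231 with an estimated correlation), among them MEPCE at -3.60 and PAF1 at -2.17. Heat shock genes fell in 15 of 17 cases (DNAJB1 at -2.68, camera adjusted p = 0.0034, adjusted p = 0.279 with an estimated correlation), MYC targets in 15 of 22 (GNL3 at -3.57, camera adjusted p = 0.0485, adjusted p = 0.231 with an estimated correlation) and NF-kB targets in 11 of 16 (NFKBIE at -4.33, IL1B at -3.69, camera adjusted p = 0.0485, adjusted p = 0.238 with an estimated correlation). The NF-kB call was lost with spike-in scaling (camera adjusted p = 0.153), although the relative median there was still -1.24.

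Transcripts of 4 classes stood above the median gene with THZ531 but below their DMSO level on the spike-in scale. Cytosolic ribosomal protein mRNAs were higher in 71 of 72 cases (relative median 1.47, camera adjusted p = 2.12e-24, adjusted p = 0.231 with an estimated correlation), and their spike-in scale median was -0.47, with 52 lower and 0 higher. Replication-dependent histone mRNAs were higher in 27 of 37 (relative median 0.95, camera adjusted p = 1.83e-05, adjusted p = 0.306 with an estimated correlation), against 5 higher and 21 lower on the spike-in scale. HIST4H4, HIST1H4C and HIST1H3G rose by 3.47, 3.07 and 3.04 and stayed above DMSO on the spike-in scale at 1.66, 1.23 and 1.21. The libraries were enriched for poly-A RNA, so for every compound histone values speak for polyadenylated transcripts and not for the total. Nuclear-encoded genes of oxidative phosphorylation were higher in 31 of 39 (camera adjusted p = 3.37e-07, adjusted p = 0.279 with an estimated correlation) and all 39 were lower on the spike-in scale. The 13 mitochondrially encoded mRNAs were all higher (camera adjusted p = 0.00485, adjusted p = 0.484 with an estimated correlation), and 12 were lower on the spike-in scale. In all, 11968 genes passed the threshold with THZ531, 5392 higher and 6576 lower (6134 and 5960 with DESeq2 size factors inside edgeR), and 6852 changed at least 2-fold. With spike-in scaling 12946 passed, 198 higher and 12748 lower. On the 2 scales 3368 genes were called in opposite directions.

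**Figure D2:**
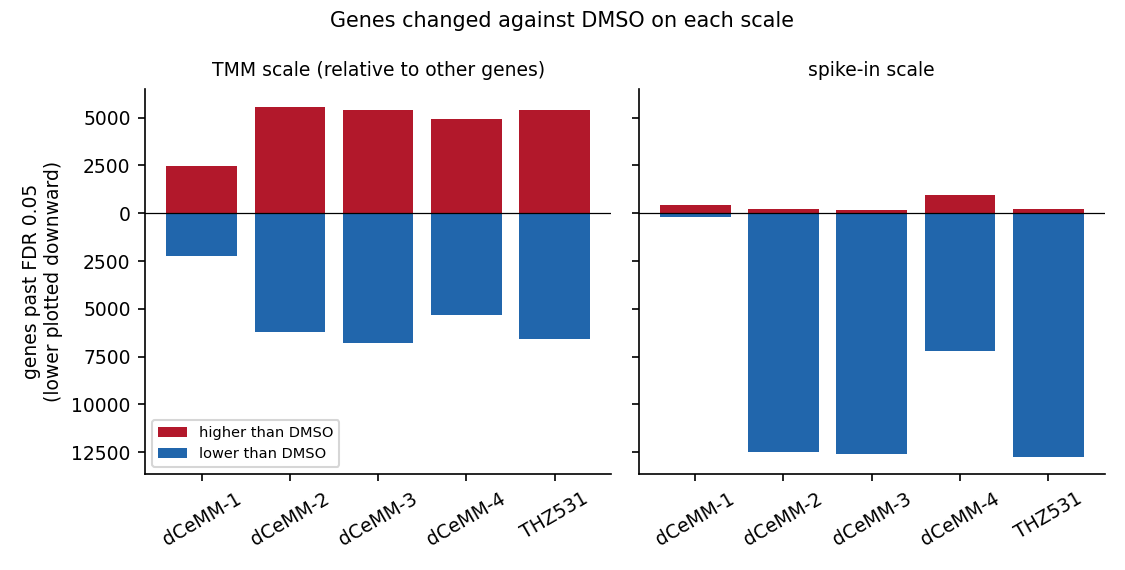
Number of genes past an adjusted p of 0.05 against DMSO in edgeR (vertical axis; higher plotted up, lower plotted down) by compound, with TMM scaling on the left and spike-in scaling on the right. With dCeMM-2, dCeMM-3 and THZ531 the higher genes number 5585, 5409 and 5392 on the TMM scale, which turn to 223, 168 and 198 on the spike-in scale.

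With dCeMM-2, the immediate early gene ARC (chromosome 8, 142611044 to 142614472, minus strand) rose by 6.67 (SE 0.16, adjusted p = 2.57e-29), from 0.701 ± 0.329 to 80.8 ± 10.1 CPM (SD, n = 3), and by 4.95 on the spike-in scale. RASD1, IER3, IER5L, SGK1, C11orf96 and PLK2 rose by 6.66, 5.79, 4.54, 4.34, 4.21 and 4.17, and CDKN1A rose by 4.09 (SE 0.08) to 329 ± 13.9 CPM. The rise of IER3 was 6.98 without DMSO replicate 2. The largest falls were those of P2RY14 (-5.45), the chemokine receptor gene CCR7 (-5.29), ZNF786 (-4.83), ZNF114 (-4.68), PAFAH2 (-4.42), NDST3 (-4.29), INKA1 (-4.25) and the cytokine gene IL1B (-4.11, SE 0.15). CCNK mRNA, encoding the cyclin that dCeMM-2 is known to degrade, was higher by 0.57 relative to the other genes (SE 0.06, adjusted p = 1.68e-10) and at -1.22 on the spike-in scale. Its partners CDK12 and CDK13 fell by 2.04 and 1.16 (SE 0.07 each), MYC by 0.75 (SE 0.06), ATR by 1.70 (SE 0.09) and BRCA1 by 1.28 (SE 0.11).

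Of 32 immediate early genes 22 rose and 4 fell with dCeMM-2 (relative median 1.23, camera adjusted p = 0.000448, adjusted p = 0.314 with an estimated correlation). On the spike-in scale 7 were higher and 16 lower. ZFP36, JUN, FOS and JUNB, at 2.83, 2.80, 2.55 and 2.53, stayed above DMSO on the spike-in scale at 1.01, 0.98, 0.74 and 0.75. Genes of homologous recombination and the DNA damage response fell in 24 of 30 cases and rose in 4 (relative median -1.08, camera adjusted p = 0.00035, adjusted p = 0.314 with an estimated correlation), including BLM at -2.13 and TOPBP1 at -1.81. Fanconi anaemia genes fell in 14 of 17 cases and rose in 3 (ERCC4 at -3.12, FANCF at -2.06, camera adjusted p = 0.0388, adjusted p = 0.327 with an estimated correlation). FANCD2, a member of that list, was higher by 0.70 (SE 0.13) and at -1.09 on the spike-in scale. Mitotic genes fell in 25 of 30 cases (CCNB1 at -2.41, camera adjusted p = 1.65e-05, adjusted p = 0.314 with an estimated correlation), heat shock genes in 13 of 17 (CHORDC1 at -1.88, camera adjusted p = 0.0348, adjusted p = 0.381 with an estimated correlation) and NF-kB targets in 11 of 16 (NFKBIE at -3.98, ICAM1 at -2.59, camera adjusted p = 0.0344, adjusted p = 0.314 with an estimated correlation, and 0.116 with spike-in scaling, where the call was lost). The NF-kB relative median was -0.94 with spike-in scaling against -0.93 with TMM, and on the spike-in scale 14 of the 16 were lower and 0 higher. Ribosomal protein mRNAs were higher in 71 of 72 cases (camera adjusted p = 9.96e-23, adjusted p = 0.314 with an estimated correlation) but lower in 57 and higher in 0 on the spike-in scale. Histone mRNAs were higher in 30 of 37 (camera adjusted p = 2.39e-05, adjusted p = 0.363 with an estimated correlation) but lower in 21 and higher in 5 on the spike-in scale. Nuclear-encoded oxidative phosphorylation genes were higher in 32 of 39 (camera adjusted p = 7.27e-07, adjusted p = 0.314 with an estimated correlation) but lower in 38 on the spike-in scale. In all, 11782 genes passed the threshold, 5585 higher and 6197 lower (5976 and 5883 with DESeq2 size factors inside edgeR), and 6487 changed at least 2-fold. By spike-in counts 12713 passed, 223 higher and 12490 lower, and 3400 were called in opposite directions.

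With dCeMM-3, MYC (chromosome 8, 127735434 to 127741434, plus strand) fell by 5.56 (SE 0.08, adjusted p = 1.17e-37), from a mean of 802 to 17.0 ± 0.547 CPM (SD, n = 3), and the cytokine gene OSM fell by 6.94 (SE 0.20). ZNF786, ZNF57, KLHL26, EFNA4 and CCR7 were lower at -5.60, -5.48, -5.42, -5.40 and -5.18. CCR7 was at -4.48 without dCeMM-3 replicate 1 and at -6.27 without dCeMM-3 replicate 2, which put ZNF57 at -6.24, and EFNA4 was at -6.02 without dCeMM-3 replicate 3. P2RY14 had 1 count over the 3 dCeMM-3 libraries against 234 in DMSO, a ratio of 210-fold lower with a 95% counting interval from 37.4-fold to 8340-fold. The largest rises were those of ARC (4.80, SE 0.19), the cystine transporter gene SLC7A11 (3.59, SE 0.10), TSSK6 (3.49), the histone gene HIST1H3G (3.38), HOXB9 (3.12), CSKMT (3.06), YPEL1 (2.91) and GSDMB (2.89). CCNK fell by 1.26 (SE 0.07), CDK12 by 2.05 (SE 0.07), CDK13 by 2.38 (SE 0.08), RBM39 by 1.34 (SE 0.08) and DCAF15 by 0.86 (SE 0.10). BRCA1 and ATR fell by 0.94 and 1.27 (SE 0.10 and 0.09), and CDKN1A was higher by 0.84 (SE 0.08) relative to the other genes and at -0.99 on the spike-in scale.

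Of 26 elongation kinases and regulators 24 fell and 0 rose with dCeMM-3 (relative median -1.21, camera adjusted p = 1.68e-05, and 0.0136 with an estimated correlation), among them MEPCE, LEO1, CTR9 and RTF1 at -3.97, -3.27, -2.33 and -1.94. MYC targets fell in 17 of 22 cases and rose in 5, with NOP16, GNL3 and WDR43 at -4.75, -4.08 and -3.88 (camera adjusted p = 0.00328, adjusted p = 0.086 with an estimated correlation). Heat shock genes fell in 16 of 17 cases and rose in 1, with HSPH1 at -3.09 (camera adjusted p = 0.000387, adjusted p = 0.28 with an estimated correlation). RNA processing genes also fell: 28 of 39 of the core spliceosome, led by PRPF4 at -4.88 (camera adjusted p = 0.0278, adjusted p = 0.415 with an estimated correlation), and 15 of 20 cleavage and polyadenylation factors, led by CSTF1 at -4.20 (camera adjusted p = 0.0225, adjusted p = 0.28 with an estimated correlation). Circadian and other short-lived transcriptional regulators fell in 16 of 20 cases and rose in 3, with NR1D1 at -4.79 and TEF at -4.02 (camera adjusted p = 0.0226, adjusted p = 0.346 with an estimated correlation). NF-kB targets fell in 12 of 16 cases (NFKBIE at -3.62, camera adjusted p = 0.0241, adjusted p = 0.28 with an estimated correlation and 0.0961 with spike-in scaling, where the call was lost), mitotic genes in 25 of 30 (AURKA at -2.70, camera adjusted p = 0.000614, adjusted p = 0.28 with an estimated correlation) and homologous recombination and DNA damage genes in 24 of 30 (PALB2 at -3.03, camera adjusted p = 0.00328, adjusted p = 0.28 with an estimated correlation). The NF-kB relative median was -1.41 with spike-in scaling against -1.40 with TMM, and on the spike-in scale 14 of the 16 were lower and 0 higher.

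The classes above the median gene with dCeMM-3 were again ribosomal protein mRNAs (72 of 72 higher, camera adjusted p = 2.4e-23, adjusted p = 0.28 with an estimated correlation), histone mRNAs (31 of 37 higher, camera adjusted p = 9.57e-07, adjusted p = 0.28 with an estimated correlation) and oxidative phosphorylation genes (31 of 39 higher, camera adjusted p = 1.59e-06, adjusted p = 0.28 with an estimated correlation). On the spike-in scale these turned to 60, 18 and 39 lower and 0, 4 and 0 higher. The 13 mitochondrially encoded mRNAs were all higher, with MT-CYB at 1.87 (SE 0.29, camera adjusted p of the list 0.00202, adjusted p = 0.419 with an estimated correlation), and 8 were lower on the spike-in scale. Of 7 lymphoid genes 6 were higher and 1 lower, among them CD79A at 1.61 (-0.16 on the spike-in scale, not called) and CD4 at 1.26 (-0.57 on the spike-in scale) (camera adjusted p = 0.0241, adjusted p = 0.28 with an estimated correlation). The lymphoid call was lost with spike-in scaling (camera adjusted p = 0.167), where the relative median was 1.27. In all, 12202 genes passed the threshold, 5409 higher and 6793 lower, and 7558 changed at least 2-fold. Scaled by spike-ins, 12776 passed, 168 higher and 12608 lower, and 3265 were called in opposite directions.

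**Figure D3:**
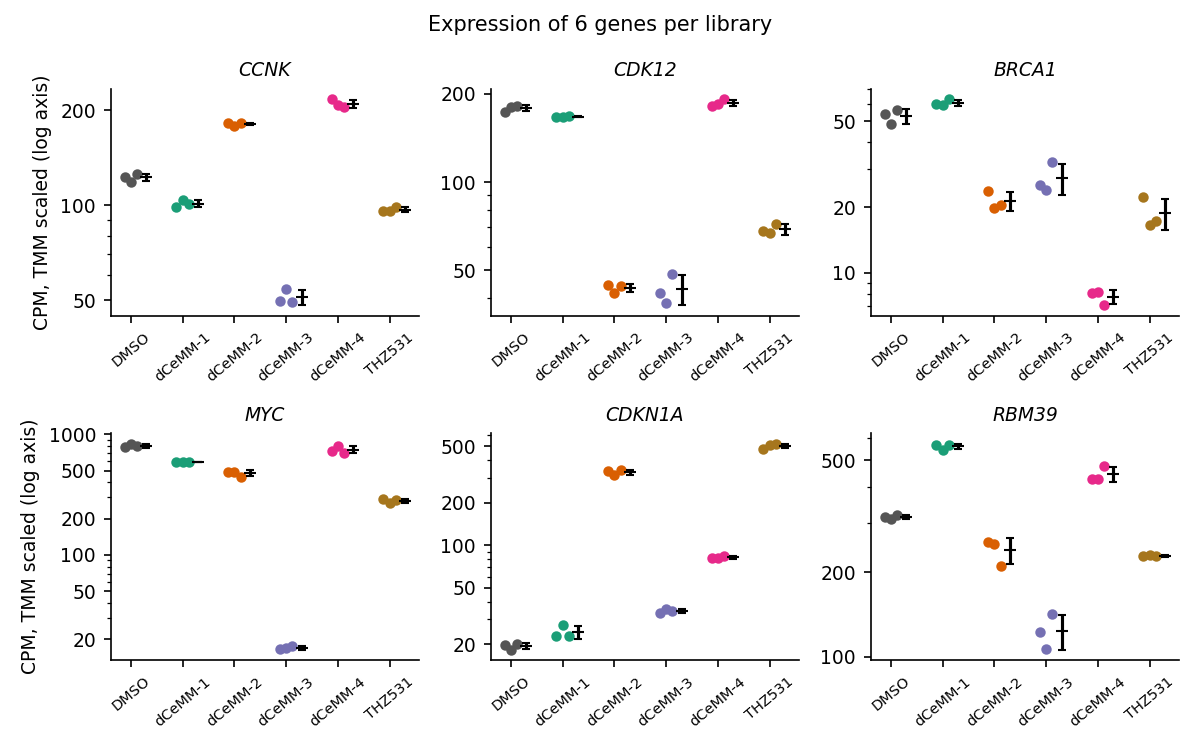
TMM-scaled CPM (log axis) of CCNK, CDK12, BRCA1, MYC, CDKN1A and RBM39 in each library (points) by group, with the mean and SD of 3 libraries as black bars. MYC stands at 17.0 CPM with dCeMM-3 against 802 in DMSO, and BRCA1 at 7.76 with dCeMM-4 against 52.7. On the spike-in scale CCNK turns lower than DMSO with dCeMM-2 and CDKN1A with dCeMM-3, and the rise of RBM39 with dCeMM-4 is lost, at -0.0592 and not called.

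With dCeMM-4, BRCA1 fell by 2.75 (SE 0.12, adjusted p = 4.68e-22), from 52.7 ± 4.04 to 7.76 ± 0.592 CPM (SD, n = 3). RCSD1 (chromosome 1, 167630093 to 167706249, plus strand) fell by 4.36 (SE 0.09), and FBXO10, CCR7, ZNF510, KRCC1, ZER1, TRAF3IP3 and LMAN2L were at -4.71, -3.91, -3.78, -3.73, -3.72, -3.67 and -3.67. KRCC1 was at -4.47 without dCeMM-4 replicate 1. The RNA-binding protein gene RBM14 rose by 2.75 (SE 0.07, adjusted p = 1.76e-27) to 481 ± 26.6 CPM. ARC, C11orf96, PLK2, ARRDC3 and the stress sensor gene SESN2 rose by 3.34, 2.78, 2.53, 2.52 and 2.47. SUMO4 and AC013394.1 were higher by 4.15 and 3.78, but they lie within or overlap TAB2 and CHD2, so their reads may not be their own. CCNK was higher by 0.78 relative to the other genes (SE 0.06), but on the spike-in scale it was at 0.20 and not called. HEXIM1 rose by 1.95 (SE 0.11) and CDKN1A by 2.09 (SE 0.08). CDK12 and MYC had log2 fold changes of 0.06 (SE 0.07, adjusted p = 0.43, called by DESeq2 at 0.18) and -0.11 (SE 0.06, adjusted p = 0.0925), and at -0.51 CDK12 turned lower on the spike-in scale. Without dCeMM-4 replicate 2, MYC was called lower at -0.17 (edgeR adjusted p = 0.0261).

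Genes of homologous recombination and the DNA damage response fell in 22 of 30 cases and rose in 4 with dCeMM-4 (relative median -0.51, camera adjusted p = 0.00611, adjusted p = 0.313 with an estimated correlation), among them RAD51D, which overlaps RAD51L3-RFFL, at -2.51 and RAD50 at -2.26. NF-kB targets fell in 11 of 16 cases and rose in 1, with RELB at -2.23 and IL1B at -2.19 (camera adjusted p = 0.00946, adjusted p = 0.293 with an estimated correlation). Circadian and short-lived regulators rose in 14 of 20 cases and fell in 2 (SERTAD1 at 2.34, camera adjusted p = 0.00611, adjusted p = 0.313 with an estimated correlation), with 6 higher and 4 lower on the spike-in scale. Immediate early genes rose in 20 of 32 cases and fell in 5 (ATF3 at 2.05, DUSP6 at 1.76, camera adjusted p = 0.00611, adjusted p = 0.313 with an estimated correlation), with 10 higher and 7 lower on the spike-in scale. Elongation kinases and regulators rose in 16 of 26 cases (CCNT2 at 1.77, camera adjusted p = 0.0463, adjusted p = 0.309 with an estimated correlation), but on the spike-in scale 3 were higher and 9 lower. SR and hnRNP splicing factors rose in 20 of 33 cases (CLK1 at 1.57, HNRNPU at 1.03, camera adjusted p = 0.00946, adjusted p = 0.313 with an estimated correlation), but on the spike-in scale 3 were higher and 9 lower. Hypoxia genes rose in 12 of 20 cases (ADM at 2.01, camera adjusted p = 0.00946, adjusted p = 0.16 with an estimated correlation), with 1 higher and 4 lower on the spike-in scale. NRF2 targets rose in 14 of 18 (SLC7A11 at 0.90, camera adjusted p = 0.0163, adjusted p = 0.313 with an estimated correlation), with 0 higher and 4 lower on the spike-in scale. Ribosomal protein mRNAs were higher in 72 of 72 cases (relative median 0.49, camera adjusted p = 1.58e-13, adjusted p = 0.313 with an estimated correlation) and 0 passed on the spike-in scale. Oxidative phosphorylation genes were higher in 25 of 39 (camera adjusted p = 0.00946, adjusted p = 0.589 with an estimated correlation), and on the spike-in scale 0 of the 39 were higher and 11 lower. In all, 10270 genes passed the threshold, 4951 higher and 5319 lower (5803 and 4668 with DESeq2 size factors inside edgeR), and 3782 changed at least 2-fold. Spike-in scaling left 8180, 948 higher and 7232 lower. The excess of lower genes rests on 1 shift of all genes by -0.56. Spike-in shares overlapped with those of DMSO, at 0.195% in dCeMM-4 replicate 2 against 0.202% in DMSO replicate 1.

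**Figure D4:**
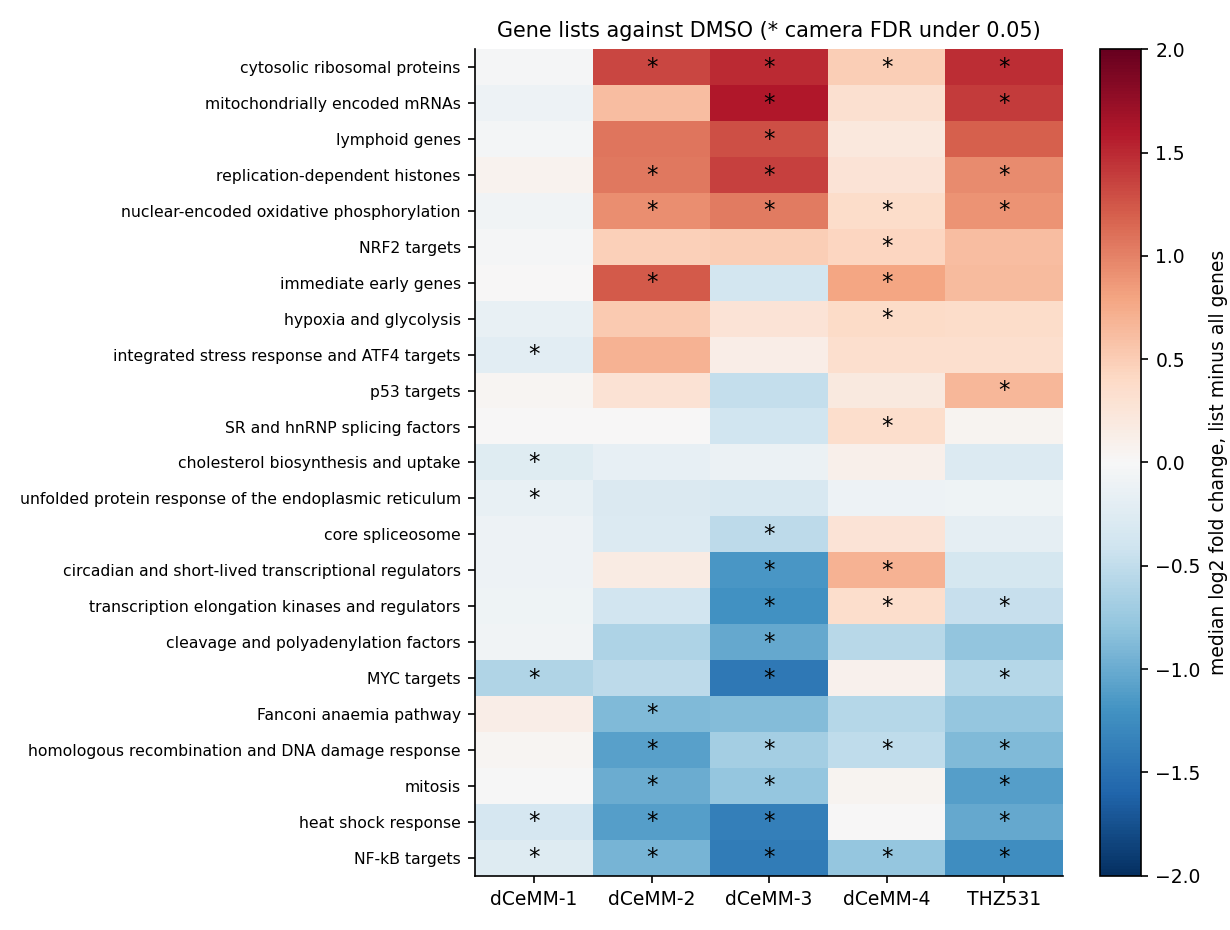
Median log2 fold change against DMSO of each gene list minus that of all genes (colour) for the lists called with at least 1 compound, by compound, with a star where the camera adjusted p is under 0.05. Of the starred calls, MYC targets with dCeMM-1 and elongation regulators with dCeMM-3 held with an estimated correlation, and the ribosomal protein, histone and oxidative phosphorylation lists have a median that turns below DMSO on the spike-in scale with dCeMM-2, dCeMM-3 and THZ531. So do the starred mitochondrially encoded mRNAs with dCeMM-3 and THZ531, immediate early genes with dCeMM-2, lymphoid genes with dCeMM-3, p53 targets with THZ531, and with dCeMM-4 the elongation, splicing factor, NRF2, hypoxia, ribosomal protein and oxidative phosphorylation lists.

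Against THZ531, whose dose of 600 nM is not matched to 10 times EC50, dCeMM-2 differed least. DUSP5 and DUSP4, phosphatases induced by MAP kinase signalling, were higher with dCeMM-2 by 2.37 and 2.08 (SE 0.14 and 0.15), together with XKR8 (2.25), RNF19B (2.25) and NXT1 (2.14). The p53 targets MDM2 and FDXR were lower at -1.69 and -1.58 (SE 0.12 and 0.09), as were EDA2R (-2.34), E2F7 (-2.08) and ZBTB38 (-1.62). Of 26 p53 targets 14 were lower and 5 higher (relative median -0.40, camera adjusted p = 0.000354, adjusted p = 0.248 with an estimated correlation), and of 32 immediate early genes 16 were higher and 1 lower (camera adjusted p = 0.00304, adjusted p = 0.518 with an estimated correlation). CCNK was higher with dCeMM-2 by 0.90 (95% interval 0.76 to 1.04) and CDK12 lower at -0.66 (-0.83 to -0.50). No difference was called for ATR at -0.11 (-0.33 to 0.10), BRCA1 at 0.20 (-0.06 to 0.45), FANCD2 at 0.02 (-0.25 to 0.30) or RBM39 at 0.07 (-0.09 to 0.23). Of 15055 genes 4569 passed the threshold, 3040 higher and 1529 lower, and 617 differed at least 2-fold, while for 11039 (73.3%) the 95% interval lay within 2-fold either way. The split depends on the scale: with DESeq2 size factors inside edgeR 2427 were higher and 2285 lower, and with spike-in scaling 1340 and 143 of 1483.

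dCeMM-3 stood below THZ531 in several inducible programmes. CDKN1A was lower at -3.87 (SE 0.07), MYC at -4.04 (SE 0.08), ID1 at -3.78 and DUSP6 at -3.55, and EDA2R had 1 count over the 3 dCeMM-3 libraries, 10.8-fold lower than DMSO with a counting interval from 1.595-fold to 461-fold. CXCL10, an interferon-induced chemokine gene, was higher by 2.75 (SE 0.07), with TUBG1, DEPDC1, SELPLG and LPCAT4 at 2.11, 1.90, 1.85 and 1.74. Immediate early genes were lower in 30 of 32 cases and higher in 0 (relative median -1.43, camera adjusted p = 3.66e-13, and 0.0237 with an estimated correlation), p53 targets lower in 21 of 26 (-1.24, camera adjusted p = 2.61e-09, and 0.006 with an estimated correlation) and metallothionein and zinc response genes lower in 7 of 8 (-1.21, camera adjusted p = 1.28e-05, and 0.0237 with an estimated correlation). Elongation regulators were lower in 19 of 26 (-0.77, camera adjusted p = 3.07e-06, and 0.006 with an estimated correlation) and MYC targets in 16 of 22 (-0.54, camera adjusted p = 1.26e-05, and 0.006 with an estimated correlation). SR and hnRNP factors were lower in 21 of 33 (camera adjusted p = 3e-06, adjusted p = 0.0545 with an estimated correlation), and the 7 genes of the cyclin K and CDK12/13 list in 5 (camera adjusted p = 0.0144, adjusted p = 0.0545 with an estimated correlation). No difference was called for FANCD2 at -0.07 (95% interval -0.34 to 0.20). In all, 6737 genes passed, 2874 higher and 3863 lower, 1525 of them at least 2-fold, and the interval lay within 2-fold for 9897 (65.7%). Spike-in scaling left 3069, 1015 higher and 2054 lower.

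dCeMM-4 and THZ531 differed in 12020 genes, 6068 higher and 5952 lower with dCeMM-4 (5923 and 6101 with DESeq2 size factors inside edgeR), 6436 of them at least 2-fold. On the spike-in scale, where the median gene moved by 1.28, 10353 were higher and 368 lower. ZNF57, USP2, EFNA4, PLEKHG3 and DLX6 were higher with dCeMM-4 by 5.25, 4.52, 4.40, 4.35 and 4.30, and IER3, FOS, DAPP1 and CSKMT were lower at -5.06, -3.60, -3.44 and -3.02. IER3 was at -6.48 without dCeMM-4 replicate 3, and ZNF57 at 6.04 without THZ531 replicate 1. CDK12 was higher by 1.44 (95% interval 1.28 to 1.59) and MYC higher (1.27 to 1.53), whereas BRCA1 was lower at -1.28 (SE 0.13) but at -0.02 on the spike-in scale. No difference was called for DDB1 at 0.08 (-0.06 to 0.22), which stood higher by 1.36 on the spike-in scale. Elongation regulators were higher in 22 of 26 cases and lower in 3 (relative median 0.99, camera adjusted p = 7.26e-05, and 0.0209 with an estimated correlation), and mitotic genes in 24 of 30 (camera adjusted p = 4.74e-05, adjusted p = 0.334 with an estimated correlation). dCeMM-1 and THZ531 differed in 12240 genes, 6863 higher and 5377 lower with dCeMM-1 (6083 and 6222 with DESeq2 size factors inside edgeR), 6898 of them at least 2-fold, and on the spike-in scale, where the median gene moved by 1.91, in 13278 higher and 157 lower. IER3, FOS, ARC, IER5L and RASD1 were lower with dCeMM-1 at -5.90, -5.57, -4.76, -4.62 and -4.61, and ZNF786, EFNA4, PPP1R10, ZNF57 and ZNF225 were higher by 5.32, 5.14, 5.10, 5.09 and 4.97, with ZNF57 at 5.89 without THZ531 replicate 1. Mitotic genes were higher with dCeMM-1 in 26 of 30 cases (camera adjusted p = 2.05e-05, adjusted p = 0.259 with an estimated correlation). Ribosomal protein mRNAs were lower in 71 of 72 (camera adjusted p = 3.57e-25, adjusted p = 0.259 with an estimated correlation) but higher in 66 on the spike-in scale. No difference was called for CCNK at 0.06 (-0.07 to 0.20), which was higher by 1.98 on the spike-in scale.

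Among the 3 compounds known as cyclin K degraders, compared at the same multiple of EC50 and the same 5 h, dCeMM-2 and dCeMM-3 were closest. DUSP5, MYC, DUSP6, CXCR4 and MSX2 were higher with dCeMM-2 than with dCeMM-3 by 5.12, 4.80, 4.65, 4.60 and 4.44 (SE 0.21, 0.08, 0.09, 0.26 and 0.30), and DEPDC1, TUBG1, SLCO4C1, CXCL10 and FAF2 were lower at -2.09, -1.83, -1.77, -1.73 and -1.39. MSX2 was at 5.06 without dCeMM-3 replicate 3. Immediate early genes were higher with dCeMM-2 in 31 of 32 cases (relative median 1.67, camera adjusted p = 3.02e-14, and 0.0252 with an estimated correlation), elongation regulators in 18 of 26 (0.87, camera adjusted p = 6.7e-06, and 0.00498 with an estimated correlation) and MYC targets in 16 of 22 (0.67, camera adjusted p = 6.7e-06, and 0.00498 with an estimated correlation). p53 targets were higher in 19 of 26 (camera adjusted p = 5.5e-05, adjusted p = 0.0575 with an estimated correlation). CCNK was higher by 1.83 (95% interval 1.68 to 1.97), and no difference was called for CDK12 at 0.01 (-0.15 to 0.18), FANCD2 at 0.09 (-0.18 to 0.36) or DDB1 at 0.13 (-0.01 to 0.27). In all, 6488 genes passed, 4008 higher and 2480 lower with dCeMM-2, 2069 of them at least 2-fold, and the interval lay within 2-fold for 9528 (63.3%). With DESeq2 size factors inside edgeR the split was 3535 higher and 3363 lower, and by spike-in counts 3426 passed, 2775 higher and 651 lower.

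dCeMM-4 differed from both in more genes. Between dCeMM-2 and dCeMM-4, 11639 genes passed, 5782 higher and 5857 lower with dCeMM-2, 5762 of them at least 2-fold, and on the spike-in scale, where the median gene moved by -1.21, 396 were higher and 10064 lower. IER3, FOS, DAPP1, ARC and RXFP1 were higher with dCeMM-2 by 4.60, 3.43, 3.34, 3.32 and 3.03, and VDR, CPTP, FDXACB1, RTN4RL1 and EFNA4 were lower at -3.44, -3.36, -3.18, -3.12 and -3.10. IER3 was at 6.03 without dCeMM-4 replicate 3, and CPTP at -4.11 without dCeMM-2 replicate 1. Elongation regulators were lower with dCeMM-2 in 22 of 26 cases (relative median -0.97, camera adjusted p = 0.000117, and 0.028 with an estimated correlation). CCNK was lower with dCeMM-2 at -0.21 (95% interval -0.35 to -0.08), and CDK12 at -2.10 (-2.26 to -1.94). Between dCeMM-3 and dCeMM-4, 12449 genes passed, 6252 higher and 6197 lower with dCeMM-3, 7737 of them at least 2-fold, and on the spike-in scale, where the median gene moved by -1.25, 805 were higher and 9833 lower. OSM, CDX2, DUSP5, GAREM1 and GATA6 were lower with dCeMM-3 at -6.30, -5.86, -5.83, -5.78 and -5.63, and DAPP1, CXCL10, RXFP1, LACTB2 and IL10RB were higher by 4.07, 3.79, 3.78, 3.55 and 3.50. Elongation regulators were lower with dCeMM-3 in 23 of 26 cases (relative median -2.24, camera adjusted p = 1.72e-05, and 0.0108 with an estimated correlation) and MYC targets in 18 of 22 (-1.66, camera adjusted p = 0.000478, and 0.0266 with an estimated correlation). BRCA1 was higher with dCeMM-3 than with dCeMM-4 by 1.81 (1.55 to 2.08) and stood at 0.59 on the spike-in scale.

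Across 15055 genes, fold changes against DMSO were most alike between dCeMM-2 and THZ531 (Pearson's r = 0.939, Spearman's rho = 0.939), followed by dCeMM-3 and THZ531 (0.899 and 0.907) and dCeMM-2 and dCeMM-3 (0.839 and 0.857). Genes are not independent replicates, and all compounds share the same 3 DMSO libraries, so each r stands beside the mean of 100 simulated pairs of unchanged groups. That mean was 0.533, 0.548 and 0.533 for these 3 pairs. dCeMM-4 gave r = 0.571 with dCeMM-2, 0.470 with THZ531 and 0.227 with dCeMM-3 (0.0906 among genes above the median expression), where simulated means were 0.562, 0.579 and 0.578. dCeMM-1 gave r from 0.133 with dCeMM-4 to 0.191 with THZ531, below simulated means of 0.620 and 0.586. Since real changes of unlike genes lower r, the covariance in excess of simulation was also computed. It was 1.44 for dCeMM-2 and THZ531, 1.59 for dCeMM-3 and THZ531, 1.41 for dCeMM-2 and dCeMM-3, 0.617 for dCeMM-2 and dCeMM-4, 0.532 for dCeMM-4 and THZ531, 0.266 for dCeMM-3 and dCeMM-4 and 0.0700 for dCeMM-1 and THZ531. dCeMM-2 and THZ531 shared 4713 higher and 5724 lower genes, where independent choice gives 2000.3 and 2706.8, and 214 moved in opposite directions. dCeMM-4 and THZ531 shared 2434 higher and 3554 lower genes, where independent choice gives 1773.2 and 2323.3, and differed in direction in 2421.

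**Figure D5:**
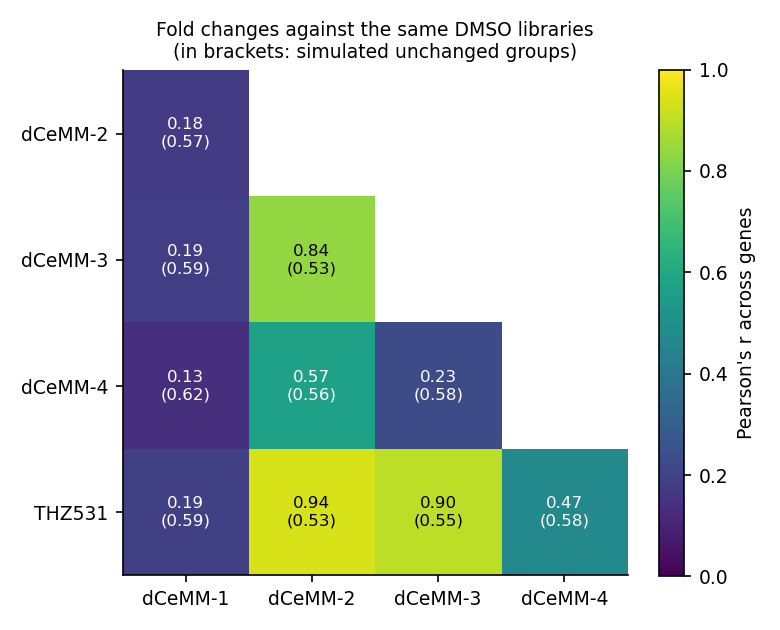
Pearson's r across 15055 genes of log2 fold changes against DMSO (TMM) for each pair of compounds (colour and upper value), with the mean r of simulated unchanged groups against the same DMSO libraries in brackets. The pair dCeMM-2 and THZ531 gives 0.939 against a simulated 0.533, and pairs with dCeMM-1 lie from 0.133 to 0.191.

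Loss of CDK12 activity is known to affect long genes, so span and exon structure were compared. The median change of 2388 genes spanning at least 100 kb minus that of 4346 genes under 20 kb was 0.06 with dCeMM-1, -0.14 with dCeMM-2, -0.13 with dCeMM-3, -0.13 with dCeMM-4 and 0.06 with THZ531 (n = 3 each, permutation p = 0.3, 0.1, 0.2, 0.1 and 0.1). SDs between libraries were 0.04, 0.06, 0.08, 0.03 and 0.01. Each gene was centred on its DMSO mean beforehand, here and for exon structure. These permutation p-values are therefore not exact and may overstate the separation from DMSO. Among genes above the median expression the value for THZ531 turned to -0.32, and those of dCeMM-2 and dCeMM-3 were -0.51 and -0.60. The direct contrast of dCeMM-2 with THZ531 placed genes under 20 kb higher with dCeMM-2 in 1248 of 4346 cases and lower in 157 (relative median 0.10, camera adjusted p = 4.65e-05, and 0.045 with an estimated correlation). Over all 15055 genes of that contrast 3040 were higher and 1529 lower, a split that became 2427 and 2285 with DESeq2 size factors inside edgeR. The 219 single-exon genes stood above the 12113 multi-exon genes by 0.18 with dCeMM-1, 0.21 with dCeMM-2, 0.34 with dCeMM-4 and 0.29 with THZ531 (permutation p = 0.1 each) and by 0.00 with dCeMM-3 (permutation p = 1, n = 3). Among genes above the median expression these differences were smaller or turned, at 0.12, 0.0366, 0.23 and 0.0355 with dCeMM-1, dCeMM-2, dCeMM-4 and THZ531 and -0.50 with dCeMM-3. Without that restriction the 3 dCeMM-3 libraries were at 0.09, -0.19 and 0.10. For the single-exon genes the camera adjusted p was 0.00244 with dCeMM-1 (0.378 with an estimated correlation) and 0.904 with dCeMM-2.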

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

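Of the tests in this part, those of reads with several positions, of the amount of spike-in added, of the loss of spliced mRNA, of intronic RNA and both on dCeMM-3 were chosen only after the result was seen.

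Spike-in sequences, which were not themselves tested as genes, stood out because their share of counts lay above that of all DMSO libraries: 0.512% with dCeMM-2, 0.542% with dCeMM-3 and 0.531% with THZ531 against 0.179% in DMSO (n = 3 each, exact permutation p = 0.1, the smallest possible). Reads with several positions, which are left out of gene counts, do not account for it, since with those reads counted in the total the lowest of the 3 ratios to DMSO was still 2.42. A larger amount of spike-in per sample with no other change would lower mitochondrially encoded counts per spike-in count (29.065 ± 6.13 in DMSO) by the same factor as all gene counts, to 9.61 ± 2.03 with dCeMM-3. All dCeMM-3 libraries lay above that, at 23.959 ± 4.60 (ratio to DMSO 0.824), so the make-up of the RNA changed there too. With dCeMM-2 (13.994 ± 4.67 against an expected 10.2 ± 2.15, ratio 0.481) such a change cannot be told from none, because the SDs overlap. The SDs also overlap with THZ531 (19.501 ± 9.78 against 9.97 ± 2.10, ratio 0.671), but every library lay above the highest expected value. The mitochondrial share was 9.75% with THZ531 against 5.14% in DMSO, with no overlap of libraries (exact permutation p = 0.1, n = 3). These values argue against an unchanged make-up of the RNA with THZ531. The amount of spike-in cancels from the comparison of observed with expected counts per spike-in count, which restates the mitochondrial share of gene counts. It therefore cannot say how much spike-in was added, and extra spike-in as the source of the larger share stays open for all 3. A lower amount of polyadenylated RNA per cell after these compounds may be the source and was not tested further, since the labels do not say how much spike-in was added per cell.

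Reads on no annotated feature, left out of the gene counts, stood out because their percent of uniquely placed reads lay above DMSO (7.14%): 8.09% with dCeMM-1, 11.7% with dCeMM-2, 11.7% with dCeMM-4 and 11.4% with THZ531 (exact permutation p = 0.1 each, n = 3). Genomic DNA would raise gene families taken as silent in these cells. The lowest ratio to DMSO of their pooled CPM was 0.354, with dCeMM-4, while dCeMM-1, dCeMM-2 and THZ531 gave 1.18, 1.06 and 1.13. With dCeMM-3, whose reads on no feature did not stand out, it was 1.67, so these families did not follow those reads. Reads on no feature in DMSO may also come from RNA, so the rise that DNA would give is not known. No conclusion on genomic DNA is drawn. With dCeMM-4, reads on no feature per spike-in count were 1.35 times those of DMSO (59.976 ± 13.6 against 44.468 ± 7.55), so a mere loss of spliced mRNA around an unchanged amount of other RNA cannot be told apart from a rise, because the SDs overlap. Intronic RNA may contribute, since genes annotated as sense intronic had a relative median of 1.46 with dCeMM-4, 1.30 with dCeMM-2 and 1.24 with THZ531, but on the spike-in scale their medians were 0.97, -0.47 and -0.66. The relative median was only 0.18 with dCeMM-1 (camera adjusted p = 0.183). It was 0.63 with dCeMM-3 (camera adjusted p = 0.0132), whose reads on no feature did not stand out. Intronic reads themselves were not analysed here.

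The rises of CDKN1A, IER3 and FOS seen with dCeMM-2 and THZ531 were smaller or missing with dCeMM-3. A larger amplitude of the same response could mean that every rise and fall grows alike. Genes higher with dCeMM-2 on the spike-in scale would then be higher still with dCeMM-3 than with THZ531. Over 223 such genes the median in that contrast was -0.62 (quartiles -1.69 and 0.21), with 99 called lower and 20 higher, which argues against such uniform growth for those 99. A larger amplitude under which rises shrink instead stays open. A larger mitochondrial share, 12.9% with dCeMM-3 against 9.75% with THZ531, would lower the other genes alike, by 0.0520 on the log2 scale from the group means and by at most 0.11 from the libraries farthest apart. Of the 223 genes, 96 had a 95% interval wholly below that. TMM scaling takes out most of such a lowering beforehand, so that count could hardly have come out otherwise and is no test of it. The largest lowering that the shares allow was smaller than the median of -0.62. Leaving mitochondrially encoded genes out of the counts put the median at -0.63. The design gives a biological alternative, that dCeMM-2, dCeMM-3 and THZ531 differ in their targets or in their effective dose, and it was not tested.

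Reads placed at several positions stood above DMSO (28.3% of all) with dCeMM-2 at 36.0%, dCeMM-3 at 41.0% and THZ531 at 37.4% (exact permutation p = 0.1 each, n = 3).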

How the results depend on the processing

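Counting THZ531 replicates 2 and 3 as 1 library and the spike-in values of named genes were chosen after seeing the data. DMSO replicate 3 had the fewest counts, 4598576, which may limit calls of weakly expressed genes against DMSO, but this was not tested. Without that library the total calls against DMSO were 4112, 11722, 12149, 10014 and 11923 for dCeMM-1 to dCeMM-4 and THZ531. Leaving out DMSO replicate 1 instead gave 4157, 11356, 11825, 9812 and 11602, and DMSO replicate 2 gave 3535, 11334, 11813, 9710 and 11533. Fewer controls can lower calls on their own, so these totals do not tell whether the shallow library limited calls. THZ531 replicates 2 and 3 were closer to counting noise (chi-square per degree of freedom 1.43) than any other pair, and with them as 1 library 11960 genes changed against DMSO. The cause was not tested.

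The total counts of changed genes stayed within 1.5 times under DESeq2, limma-voom, DESeq2 size factors inside edgeR, no low-count filter, 1 CPM in 3 libraries, only the 2 groups compared, a replicate block and with each library left out. Leave-one-out counts against DMSO ranged from 3535 to 4157 for dCeMM-1, 11334 to 11722 for dCeMM-2, 11805 to 12149 for dCeMM-3, 9710 to 10014 for dCeMM-4 and 11533 to 11923 for THZ531. A fold change of at least 2 left, by construction, 409, 6487, 7558, 3782 and 6852 genes for dCeMM-1 to dCeMM-4 and THZ531 against DMSO. Against THZ531 it left 6898, 617, 1525 and 6436 for dCeMM-1 to dCeMM-4, with 2069, 5762 and 7737 for dCeMM-2 against dCeMM-3, dCeMM-2 against dCeMM-4 and dCeMM-3 against dCeMM-4. Spike-in scaling lowered 4 counts by more than 1.5 times: 628 for dCeMM-1 against DMSO, 1483 and 3069 for dCeMM-2 and dCeMM-3 against THZ531 and 3426 for dCeMM-2 against dCeMM-3. The cause was not tested.

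Of 400 values of named genes, 304 kept direction and side of the threshold with spike-in scaling and 50 changed sign, as follows from the shift of all genes, 27 of them past the threshold on that scale. With dCeMM-2: CCNK -1.22, RPL22 -0.26, COX7C -0.53, DCAF15 -1.45, RPL13A -0.12, FANCD2 -1.09, COX6C -0.58, DDB1 -1.75, RPS9 -0.28, UQCRH -0.43, HEXIM1 -0.76, NDUFA4 -0.39 and RPL39 -0.31. With dCeMM-3: CD4 -0.57, CD79A -0.16, NKG7 -0.61, RPL22 -0.32, CDKN1A -0.99, COX7C -0.50, RPL13A -0.19, RPL11 -0.33, FANCD2 -1.20, UQCRB -0.61, COX6C -0.74, CD3D -0.69, UQCRH -0.51, MT-CYB -0.0029, MT-CO1 -0.25, MT-ND3 -0.26, RPL39 -0.38 and MT-CO3 -0.34. With dCeMM-4: RBM39 -0.0592, CDK12 -0.51 and DDB1 -0.25. With THZ531: RPS20 -0.35, RPL22 -0.21, NDUFA1 -0.55, COX7C -0.44, RPL13A -0.18, FANCD2 -1.15, UQCRB -0.59, COX6C -0.54, DDB1 -1.61, ZMAT3 -0.24, HEXIM1 -0.39, MT-CYB -0.31, MT-ND5 -0.52, MT-CO1 -0.41, MT-ND3 -0.41 and RPL39 -0.28. DESeq2 gave the same call for 395 of 400, with CDK12 (0.18), CDK13 (0.27) and FANCD2 (0.34) newly called with dCeMM-4 and DDB1 (-0.19) with dCeMM-1, and HEXIM1 (-0.14) lost with dCeMM-3. HEXIM1, lower with dCeMM-3, lost its call without DMSO replicate 2, DMSO replicate 3 or dCeMM-3 replicate 2 (-0.29, -0.28 and -0.18).

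Of the called gene lists 6, 9, 14, 10 and 11 against DMSO (dCeMM-1 to dCeMM-4, THZ531), 2, 7, 11, 5 and 9 kept their call with spike-in scaling and 1, 0, 1, 0 and 0 with an estimated correlation. Spike-in scaling ended the calls of NF-kB targets (dCeMM-1, dCeMM-2, dCeMM-3 and THZ531), oxidative phosphorylation (dCeMM-2 to dCeMM-4 and THZ531), ATF4 targets, the unfolded protein response and cholesterol genes (dCeMM-1), lymphoid genes (dCeMM-3) and elongation regulators, SR and hnRNP factors, NRF2 targets and hypoxia genes (dCeMM-4). It gave a call to 12 lists without one: elongation regulators, MYC targets and circadian regulators (dCeMM-2), the core spliceosome (dCeMM-2 and THZ531), fibroblast and epithelial genes (dCeMM-2, dCeMM-3 and THZ531), SR and hnRNP factors (dCeMM-3), histones (dCeMM-4), and cleavage factors and immediate early genes (THZ531). Where spike-in scaling ended a call, the relative median could stay nearly the same. For NF-kB targets it was -0.94 against -0.93 with TMM (dCeMM-2) and -1.41 against -1.40 (dCeMM-3). For oxidative phosphorylation it was 0.93 on both scales (dCeMM-2) and 1.01 against 1.04 (dCeMM-3). Leave-one-out kept 31 of 36 calls with dCeMM-1 and every call with the other 4 compounds, and in 30 cases a list without a call gained one. These were fibroblast and epithelial genes (dCeMM-2 and THZ531), apoptosis regulators (dCeMM-2 and THZ531), ATF4 targets (dCeMM-2), the RBM39 and DCAF15 list and SR and hnRNP factors (dCeMM-3), histones (dCeMM-1 and dCeMM-4), the core spliceosome (dCeMM-1), p53 targets (dCeMM-4), and Fanconi anaemia and immediate early genes (THZ531). At an adjusted p under 0.05, fry called 9 lists in the direction opposite to that of camera, which did not call them (mean log2 fold change in brackets): with dCeMM-2 SR and hnRNP factors (-0.12), interferon (-0.19) and megakaryocyte genes (-0.0511), with dCeMM-3 hypoxia (-0.37), interferon (-0.24) and megakaryocyte genes (-0.47), with dCeMM-4 the RBM39 and DCAF15 list (-0.13) and with THZ531 SR and hnRNP factors (-0.14) and megakaryocyte genes (-0.46). Directions can differ because fry tests a list against 0 and camera tests it against the other genes. The cause of the other changes of calls was not tested.

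The difference of long minus short genes moved for genes above the median expression, to -0.51, -0.60, -0.18 and -0.32 with dCeMM-2, dCeMM-3, dCeMM-4 and THZ531. For at least 50 kb against under 10 kb it was -0.42, -0.28, -0.21 and -0.18, and in 3 bins of exonic length -0.32, -0.32 and -0.17 with dCeMM-2, dCeMM-3 and THZ531, so the sign with THZ531 depends on this choice. With 1 library left out, at least 100 kb against under 20 kb ranged from 0.04 to 0.08 with dCeMM-1 and 0.04 to 0.07 with THZ531. The range was -0.17 to -0.11 with dCeMM-2, -0.17 to -0.09 with dCeMM-3 and -0.15 to -0.10 with dCeMM-4. Single-exon minus multi-exon genes above the median expression gave 0.12, 0.0366, -0.50, 0.23 and 0.0355 (dCeMM-1 to dCeMM-4, THZ531), and leaving out 1 library moved the dCeMM-2 value between 0.19 and 0.31, the latter without dCeMM-2 replicate 3. The dCeMM-3 value over all expression levels moved between -0.03 and 0.11. The correlation of dCeMM-3 with dCeMM-4 fell to 0.0906 among genes above the median expression. The cause was not tested.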

Other observations

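The tests of gene classes in this part were chosen only after the results were seen, and the receptor test was prompted by the rises of CYP1B1 and TIPARP.

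Zinc finger genes moved down together with 4 of the compounds. Of 391 protein-coding genes named ZNF, most of them repressors of transcription, 313 fell and 32 rose with dCeMM-2 (relative median -1.28, camera adjusted p = 3.11e-11, and 0.0218 with an estimated correlation). With dCeMM-3 322 fell and 25 rose (-1.54, camera adjusted p = 3.04e-11, and 0.0225 with an estimated correlation), and with THZ531 328 fell and 29 rose (camera adjusted p = 4.8e-13, and 0.0147 with an estimated correlation). With dCeMM-4 216 fell and 81 rose (-0.51, camera adjusted p = 0.00139, adjusted p = 0.402 with an estimated correlation). With dCeMM-1 129 rose and 12 fell (0.18, camera adjusted p = 8.07e-05, adjusted p = 0.162 with an estimated correlation). Processed pseudogenes were called higher relative to the other genes in 542, 539 and 597 of 847 cases with dCeMM-2, dCeMM-3 and THZ531 (camera adjusted p with an estimated correlation 0.00866, 0.00387 and 0.00439), but their spike-in scale medians were -0.56, -0.64 and -0.56. Such pseudogenes are copies of spliced mRNAs, so reads counted for them may not be their own, which was not tested. Long intergenic RNAs were higher in 226, 230 and 227 of 428 cases (0.0150, 0.00387 and 0.00532 with an estimated correlation), with spike-in scale medians of -0.87, -0.88 and -0.89. Of 127 sense intronic genes 79 were higher and 11 lower with dCeMM-4 (camera adjusted p = 2.24e-06, adjusted p = 0.164 with an estimated correlation), with a spike-in scale median of 0.97. With dCeMM-2 75 were higher and 15 lower (camera adjusted p = 8.2e-05, adjusted p = 0.0726 with an estimated correlation) and with THZ531 72 and 14 (camera adjusted p = 2.4e-05, adjusted p = 0.0588 with an estimated correlation), but their medians fell below DMSO on the spike-in scale at -0.47 and -0.66.

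Marker lists of other cell types gave 1 call against DMSO, the lymphoid genes with dCeMM-3 described above (median log2 fold change 1.14). With dCeMM-2 and THZ531 the 7 lymphoid genes had medians of 1.05 and 1.10, each with 5 higher and 1 lower (camera adjusted p = 0.0875 and 0.0616). Fibroblast and epithelial genes had camera adjusted p = 0.717, 0.0554, 0.0668, 0.506 and 0.0544 with dCeMM-1 to dCeMM-4 and THZ531. They gained a call with dCeMM-2 without DMSO replicate 3 or dCeMM-2 replicate 1 (camera adjusted p = 0.0420 and 0.0448) and with THZ531 without DMSO replicate 3 or THZ531 replicate 1 (0.0372 and 0.0490). Spike-in scaling also gave them a call with dCeMM-2, dCeMM-3 and THZ531 (camera adjusted p = 0.0264, 0.0097 and 0.0254), relative to the other genes, while their medians on that scale were -0.57, -0.74 and -0.65. The 4 measured erythroid genes had camera adjusted p = 0.324, 0.111, 0.0662, 0.382 and 0.0616. Myeloid genes had 0.842, 0.708, 0.804, 0.836 and 0.805, and megakaryocyte genes 0.907, 0.863, 0.88, 0.628 and 0.941.

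The rise of CYP1B1 and TIPARP with dCeMM-1 led to the hypothesis that aryl hydrocarbon receptor target genes rise together. Of 6 other measured targets 2 rose, CYP1A1 by 1.32 (SE 0.09, edgeR adjusted p = 2.14e-14) and the receptor repressor AHRR by 0.94 (SE 0.09, edgeR adjusted p = 2.02e-10). SLC7A5 fell by 0.41, and NQO1 at 0.23 (edgeR adjusted p = 0.145), LRRC25 at 0.47 (0.0906) and NFE2L2 at 0.06 (0.55) were not called. AHRR was lower with dCeMM-2, dCeMM-3, dCeMM-4 and THZ531 at -1.78, -1.95, -1.75 and -1.49. TIPARP was higher also with dCeMM-2 at 1.35 (-0.41 on the spike-in scale) and dCeMM-4 at 1.34 (0.79), and CYP1B1 with dCeMM-2 at 1.08 (-0.65). Activation of the receptor by dCeMM-1 may explain the CYP1 genes and AHRR, as a hypothesis found and tested on the same data.

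For every comparison, 1 of the 10 splits of the 6 libraries gave as many changed genes in edgeR, the real split itself, and with 10 splits a share under 0.05 cannot be reached. The real counts from the 2 groups alone were 5418, 11249, 11533, 10124 and 11380 for dCeMM-1 to dCeMM-4 and THZ531 against DMSO, and 11852, 4791, 6005 and 11548 for dCeMM-1 to dCeMM-4 against THZ531. They were 5767, 11267 and 11829 for dCeMM-2 against dCeMM-3, dCeMM-2 against dCeMM-4 and dCeMM-3 against dCeMM-4. The highest other split gave 0 genes in each comparison, with at most 576, 52, 28, 85, 46, 27, 574, 267, 34, 528, 38 and 22 genes at an unadjusted p under 0.05 in edgeR, in the same order.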
